A study of Mus musculus with 31 samples.

How the data were processed

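The series held 31 libraries of mouse embryonic stem cells carrying a conditional Dicer1 gene, which encodes the enzyme that cuts microRNA precursors into mature microRNAs. Small RNA was sequenced in 15 libraries, 3 for each of days 0, 4, 8, 10 and 12 of treatment with 800 nM 4-hydroxytamoxifen (4-OHT), the drug that triggers loss of the gene. Newly made RNA was labelled with 200 uM 4-thiouridine (4sU) for 10 or 15 minutes, and labelled and unlabelled RNA were separated, in 16 libraries from 2 wild-type (WT) and 2 Dicer-depleted cultures. The sample titles call the unlabelled fraction total and the characteristics call it preexisting; it is called preexisting here. The labels give 8 days of treatment for WT and depleted cells alike.

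For small RNA, the deposited table holds raw counts per mature microRNA locus with no normalization. Per the labels, adapters were removed with cutadapt 1.8, reads were aligned to mm10 with Bowtie2, and HTSeq counted them over miRBase 21. The table has 2045 microRNA entries for 1907 identifiers and 5 HTSeq summary lines for unassigned reads, which were kept out of the microRNA tests and used for library totals. Reads below the mapping quality limit were not assigned by the authors, so microRNAs with several identical copies can be undercounted. All reads per library, assigned and unassigned, came to 11134202 to 16216368, and reads on microRNAs to 51984 to 2366940.

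For 4sU RNA, the deposited values are named TPM, yet every column sums to 10000000, so the deposited unit is a signal of which 10 units make 1 TPM. Values were divided by 10 and are given as TPM. Per the labels, reads from ribosomal RNA were removed with STAR 2.5.0, and the rest were aligned to exonic and intronic sequences and quantified with RSEM. The deposited table has 121429 exonic and 91702 intronic entries; 110366 of the exonic ones matched a gene of GENCODE M21, and their values were summed per gene. Unmatched entries, with 5.57 to 7.60% of a library's signal, were tested but not named. The sequencing depth of the 4sU libraries is unknown, so no counting interval can be given for them.

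MicroRNAs were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr by day) in 1 model of all 15 libraries, which left 260 microRNAs, and DESeq2 1.42.0 was an alternative. TMM compares microRNAs with one another; a second scaling used all reads of a library as its size and is given as RPM, reads scaled to all reads of the library. Total microRNA counts were compared with exact two-sided permutation tests, for which 3 against 3 libraries cannot go below p = 0.1. A trend over days used 100000 permutations.

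Genes were tested with limma 3.58.1 (trend) on log2(TPM + 1). The 10 and 15 minute libraries of a culture were averaged, so each genotype had n = 2 cultures per fraction. A gene needed a mean of at least 1 TPM over the 16 libraries, which left 21821 genes. The comparisons were depleted against WT in the labelled fraction, in the preexisting fraction, in the preexisting to labelled ratio and in intronic signal, labelled against preexisting in WT, and 15 against 10 minutes of labelling. All p-values are two-sided. Those called adjusted were adjusted by Benjamini and Hochberg, with a threshold of 0.05. P-values of edgeR, limma and permuted libraries measure spread between these samples and no wider population of cultures. Camera, random gene sets, permuted site labels and Fisher's exact test compare genes with other genes, and the sign-flip test compares precursors. R 4.3.3, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.

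Before the data were examined, 23 gene lists, 15 microRNA lists and 12 microRNA seed families were fixed, along with the tests and most of the alternatives. Lists were tested with camera at a correlation of 0.01, and again with the correlation estimated from the data. Predicted targets were 10078 mRNAs scored for a 7-base seed site in the 3′ UTR and 1068 long noncoding RNAs (lncRNAs) scored over the spliced transcript. Besides camera, each target set was set against 10000 random gene sets matched on expression and length, with matching on GC content as a check; the smallest p these can give is 2e-04. Random sets and permuted site labels treat genes as independent and do not resample cultures. Control families were those of microRNAs not known to be made in embryonic stem cells (miR-122, miR-124, miR-1, miR-133 and miR-208).

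Named microRNAs were members of the lists, the 10 most abundant at day 0, and per comparison the 10 largest rises and 10 largest falls among those past the threshold with a mean of at least 50 CPM, counts scaled to microRNA reads, in either day. Named genes were Dicer1, members of the lists, and per comparison the 12 largest rises and 12 largest falls among those past the threshold with at least 5 TPM in the higher group and no overlap between the genotypes' cultures; where none passed, the genes of smallest p were taken. Any other gene is said to have been chosen after its values were seen. Not all genes that met this rule are reported here.

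The numbers of replicates were checked for pairing. Of 30 pairs of small RNA libraries that share a number, 12 had a correlation above 0.1, and the lowest was -0.19. The median was 0.0789 against -0.0615 for pairs of different numbers, and 13 of the 15 libraries correlated best with one of their own number, so a weak shared part is not excluded. In the 4sU data the difference between cultures 1 and 2 correlated across genes at 0.162 between genotypes in labelled RNA and at 0.219 in preexisting RNA. Between the 2 fractions of the same cultures this difference correlated at 0.397 in WT and at 0.0512 in depleted cells. Replicates were not paired in the models, and a replicate block was an alternative. The 2 fractions of a culture entered the gene model as separate values and were paired only in the ratio. Labelled against preexisting in WT therefore does not rest on independent samples.

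The tests were tried on simulated data. For microRNAs, 79.1% of 2-fold and 100% of 4-fold changes placed in simulated counts were recovered, with 6 false calls among 508 entries. Every simulated library had the size of a day 0 library, and most entries were unchanged. Real day 8 libraries held 117027 to 220186 microRNA reads, and 260 entries were tested. These rates therefore do not describe the real day 8 test. For genes in the preexisting fraction, 16.4% of 2-fold, 67.2% of 4-fold and 87.9% of 8-fold changes were recovered, with 8 false calls among 21821. Changes were placed only in genes at about 5 TPM or more in WT. Noise was drawn independently for each gene and fraction, whereas the real culture difference correlated at 0.397 between fractions in WT. The gene rates and false calls are therefore no estimate for the real test either. Alternatives covered scaling, filters, pseudocounts, tools, the unit of replication, single labelling times, and leaving out each replicate. Mitochondrially encoded mRNAs had no entry in the table, and a two-cell-like list had 1 gene above the filter; neither was tested, nor was the miR-451a list (85 reads) or the let-7 list (1 microRNA above the filter).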

Results

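The libraries fell into 13 groups. Small RNA libraries covered days 0, 4, 8, 10 and 12 of 4-OHT treatment of the cells, with 3 libraries per day; day 0 was untreated and carried the same "Dicer depleted" label. The 4sU libraries covered labelled and preexisting RNA of WT and Dicer-depleted cells at 10 and 15 minutes of labelling, with 2 libraries per group. The title of the series concerns whether translation is needed for mRNA decay by microRNAs, which makes coding mRNAs and lncRNAs with microRNA sites the contrast of interest. Small RNA libraries held 11134202 to 16216368 reads, and the depth of the 4sU libraries is unknown.

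The first question was how fast mature microRNAs disappeared once Dicer1 was deleted. MicroRNAs made up 18.8% ± 2.75 of all small RNA reads at day 0 (SD, n = 3), 11.3% ± 1.71 at day 4, 1.12% ± 0.316 at day 8, 0.586% ± 0.101 at day 10 and 0.448% ± 0.147 at day 12. The share at day 8, the day of the 4sU experiment according to the labels, was 16.7-fold below day 0, and at day 12 it was 41.9-fold below. The share was 2.51-fold lower at day 12 than at day 8. Each of these days was separated from its reference without overlap (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Over all 15 libraries, day and log2 share had Pearson's r = -0.97 and Spearman's rho = -0.96 (permutation p = 1e-05 each, the smallest that 100000 permutations give); without the 2 libraries farthest from the median day, r was -0.96. No sequencing batch is given in the labels, so no value within batches could be computed.

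**Figure D1:**
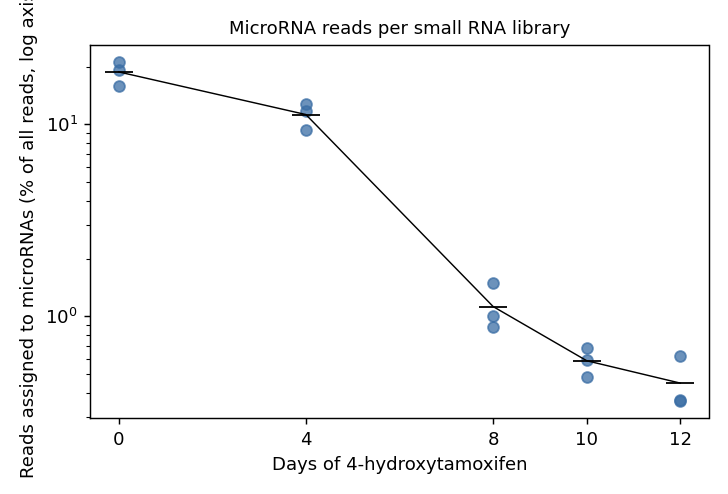
Percent of all small RNA reads that fell on microRNAs in each of 15 libraries, by day of treatment, with a line through the means of 3 libraries per day. The mean falls from 18.8% at day 0 to 0.448% at day 12.

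Day 4 was compared with day 0 to find the microRNAs lost first. The miR-302 cluster, a family active in pluripotent cells, kept 15.5% of its day 0 RPM (its reads scaled to all reads of the library), against 60.0% for the miR-290 cluster, the most abundant family known from mouse embryonic stem cells. Relative to other microRNAs 7 of 7 tested members of miR-302 fell, and also 7 of 7 when adjusted over the list alone. miR-302a-3p went from 865 ± 90.2 to 119 ± 16.6 RPM (n = 3; log2 change in RPM -2.86, SE 0.304, edgeR adjusted p = 7.87e-08). The Dlk1-Dio3 cluster, an imprinted group of microRNAs, kept 34.1%, and 25 of 38 members fell and 2 rose relative to other microRNAs (26 and 2 adjusted over the list alone), while in RPM 35 fell and 0 rose. Among the 10 most abundant microRNAs, retention ran from 30.6% for miR-298-5p to 114% for miR-22-3p, whose log2 change in RPM was 0.20 (adjusted p = 0.62). A few microRNAs rose under both scalings: miR-100-5p went from 1.53 ± 0.315 to 8.11 RPM, or 531% (log2 2.39, adjusted p = 0.000151), and miR-125b-1-3p from 10.9 ± 0.509 to 41.6 ± 10.8 RPM (log2 1.93, adjusted p = 4.32e-06). The miR-302 list (camera adjusted p = 1.64e-05; adjusted p = 0.351 with an estimated correlation) and the Dlk1-Dio3 list (adjusted p = 0.0178; adjusted p = 0.484 with an estimated correlation) were lower as groups. The miR-15 family kept 78.0% and was higher relative to others in 8 of 10 members, also adjusted over the list alone, while in RPM 1 was higher and 1 lower (adjusted p = 0.0407; adjusted p = 0.484 with an estimated correlation). With total microRNA counts as library size, the miR-302 list (adjusted p = 2.75e-05) and the Dlk1-Dio3 list (adjusted p = 0.00711) passed and the miR-15 list did not (adjusted p = 0.0679). In all, 79 microRNAs were higher and 90 lower relative to the others, and in RPM 8 were higher and 133 lower, with a median log2 change of -0.79. Without replicate 1 the relative count of 169 went to 108, with 24 higher and 84 lower.

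At day 8 the abundant microRNAs of these cells were nearly gone. miR-295-3p, a leading member of the miR-290 cluster, went from 20702 RPM to 472 ± 126 RPM (2.28% kept; log2 -5.46, SE 0.292, adjusted p = 1.47e-14), and miR-92a-3p, of the miR-17 and miR-106a clusters, kept 2.97%. The Dlk1-Dio3 cluster kept 1.18% (24 lower and 3 higher relative to others, the same numbers adjusted over the list alone, and all 38 lower in RPM), and miR-302 kept 1.41% (6 of 7 lower, and 6 adjusted over the list alone). The miR-182 cluster kept 7.02% and so was higher relative to other microRNAs in 4 of 5 members, although none was higher in RPM. miR-183-5p, for example, kept 14.7% (559 ± 239 RPM). The miR-15 family kept 9.69% and was likewise higher relative to others in 8 of 10 members, while 9 were lower in RPM. Of the 8, miR-16-5p was also higher in RPM, from a low level of 2.81 ± 0.978 RPM at day 0. It was at 9.10 ± 7.71 RPM at day 8 (324% of day 0, and 178% without replicate 1). The 4 lists passed camera with adjusted p = 0.0178 (Dlk1-Dio3), 0.0235 (miR-302 and miR-182) and 0.0407 (miR-15), and none did with an estimated correlation (adjusted p = 0.484, 0.484, 0.351 and 0.484). With total microRNA counts as library size none of the 4 passed either (adjusted p = 0.0973, 0.0803, 0.0727 and 0.0901). Relative to other microRNAs 89 were higher and 84 lower, yet of the 89, 63 were lower in RPM and 10 higher. In RPM 234 of 260 were lower, with a median log2 change of -4.94.

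At days 10 and 12 the same clusters kept shrinking in RPM. At day 12 the miR-290 cluster kept 0.389% of its day 0 RPM, the miR-302 cluster 0.385%, the miR-17 cluster 0.318%, the miR-106a cluster 0.307%, the miR-106b cluster 0.338%, the miR-200 family 0.311%, the Sfmbt2 intronic cluster 0.220%, the miR-30 family 0.704% and mirtrons, which skip the Drosha step, 0.647%. None of these 9 lists passed camera at day 12. The Dlk1-Dio3 cluster kept 0.252% at day 10 and 0.142% at day 12, when 30 of 38 members were lower and 3 higher relative to others, the same numbers adjusted over the list alone, and all 38 lower in RPM (camera adjusted p = 0.00239; adjusted p = 0.484 with an estimated correlation). With total microRNA counts as library size, the list did not pass at days 10 and 12 (adjusted p = 0.126 and 0.0730). miR-127-3p, a member, kept 0.0937% at day 12 (5.38 ± 5.67 RPM; log2 -10.05, SE 0.623, adjusted p = 1.42e-14). Without replicate 2 of day 12 it kept 0.0368% (2.12 RPM) and the cluster 0.0869%. The miR-182 cluster was again the least reduced of the abundant groups, with 4.15% at day 10 and 3.28% at day 12 (adjusted p = 0.029 and 0.0235; adjusted p = 0.351 with an estimated correlation at both, and 0.0727 and 0.0679 with total microRNA counts). miR-182-5p, the most abundant microRNA at day 0 with 38078 RPM, kept 3.04% at day 12, but 1.66% without replicate 1 (1.94% for the cluster), which alone held 29132 of its reads against 8645 and 9799 in the other libraries. The miR-15 family kept 5.63% and 3.01% (adjusted p = 0.0381 and 0.0376; adjusted p = 0.484 with an estimated correlation at both, and 0.101 and 0.138 with total microRNA counts). Relative to other microRNAs, 88 were higher and 100 lower at day 10, and at day 12 180 changed, 77 of them higher. In RPM 6 and 3 were higher, and 235 and 240 lower.

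Day 12 was compared with day 8 to see whether the profile still moved after the day of labelling. miR-295-3p fell by a further 3.11 on the log2 scale of RPM (adjusted p = 5.62e-10), miR-92a-3p by 3.27 (adjusted p = 5.62e-10) and miR-96-5p by 3.29 (adjusted p = 7.95e-07). miR-182-5p fell by 1.03 (adjusted p = 0.0164) and miR-183-5p by 1.46 (adjusted p = 0.000149). miR-6240 was the only microRNA entry that rose in RPM, from 198 ± 29.0 to 500.1 ± 20.9 RPM (log2 1.34, adjusted p = 0.000452), and 197 were lower. Relative to other microRNAs 43 were higher and 48 lower; without replicate 1 the total of 91 went to 52, and it was 58 with the libraries of these days alone. Across all days 242 of 260 microRNAs changed relative to others and 248 in RPM.

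**Figure D2:**
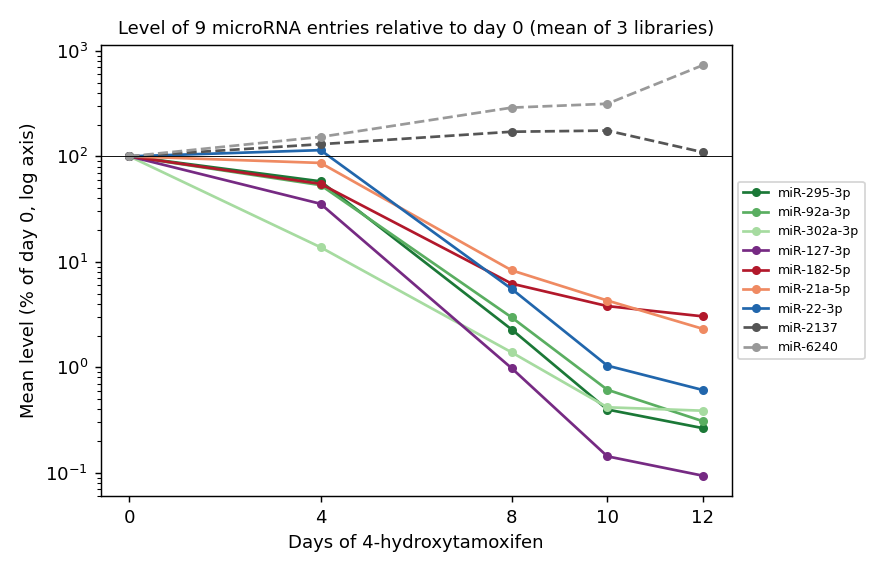
Percent of day 0 RPM (reads scaled to all reads of the library) that remained at each day for 9 microRNA entries, on a log axis, as means of 3 libraries. miR-127-3p and miR-295-3p end below 0.3% at day 12, while miR-2137 ends at 109% and miR-6240 at 732%.

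A small set of entries did not follow the loss. Of 260 tested, 29 kept at least 25% of their day 0 RPM at day 12, and 208 kept under 5%; the median was 0.571%. The listed entries suspected beforehand to lie in ribosomal or other abundant RNA kept 180% at day 8, 185% at day 10 and 156% at day 12 as a sum. Of its 3 tested entries, miR-2137 went from 868 ± 148 to 950 ± 212 RPM at day 12, miR-6240 from 68.3 ± 20.8 to 500.1 ± 20.9 RPM, and miR-6236 from 25.9 ± 7.05 to 52.0 ± 15.3 RPM (n = 3). All 3 were higher relative to other microRNAs on each day (camera adjusted p = 0.0455, 0.0178, 0.0229 and 0.0178; adjusted p = 0.484 with an estimated correlation each day). With total microRNA counts the list did not pass at day 4 (adjusted p = 0.0747) and passed on the other days (adjusted p = 0.00711, 0.00711 and 0.00620). At day 12 miR-182-5p made up 23.5% ± 10.7 of the microRNA reads that were left, miR-2137 21.7% ± 2.90, miR-6240 11.9% ± 3.32, miR-5099 8.62% ± 1.46 and miR-6539 7.74% ± 1.21. Without the listed entries, 1.59% of day 0 microRNA RPM was left at day 12 in place of 2.39%. miR-451a, which matures without Dicer, had 85 reads over all 15 libraries and could not be followed.

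In the 4sU data the depletion was visible in Dicer1 itself (chromosome 12, 104687742 to 104751952, mm10). In preexisting RNA, Dicer1 went from 16.5 ± 1.42 TPM in WT to 2.69 ± 0.671 TPM in depleted cells (SD, n = 2 cultures; log2 -2.29, SE 0.248, limma adjusted p = 0.0347). In labelled RNA it was at 8.22 ± 0.899 TPM in WT and 2.87 ± 0.617 TPM in depleted cells (log2 -1.26, adjusted p = 0.143). Its intronic signal in labelled RNA was 2.29 ± 0.0509 TPM in WT and 2.99 ± 0.423 TPM in depleted cells. Among other members of the silencing machinery, preexisting Ago1 was at 16.2 TPM in WT and 43.3 TPM in depleted cells (adjusted p = 0.083) and Tnrc6a, which links Argonaute to deadenylation, at 9.60 and 23.4 TPM (adjusted p = 0.0563). The list of 12 did not pass camera in preexisting RNA (adjusted p = 0.608).

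The preexisting fraction, which holds RNA made before labelling, was compared to find genes whose level changed with Dicer loss. Named targets of the miR-290 family rose: Cdkn1a, the cell cycle inhibitor p21, went from 45.4 ± 18.3 to 176 ± 9.06 TPM (n = 2; log2 1.99, SE 0.300, adjusted p = 0.0426). Mbd2, a methyl-CpG binding protein, went from 5.13 ± 1.04 to 21.7 ± 7.65 TPM (log2 1.88, adjusted p = 0.0426), and Ei24, a p53-induced gene, from 73.0 ± 4.86 to 159 ± 3.86 TPM (log2 1.11, adjusted p = 0.0426). The largest rise among named genes outside the repeat-rich genes described separately was that of 9530068E07Rik (17.5 ± 1.74 to 130 ± 23.9 TPM, log2 2.84, adjusted p = 0.0193). Dpp4, a membrane peptidase, rose from 3.39 to 23.6 TPM and Tcf7l2, a transcription factor of Wnt signalling, from 94.8 to 279 TPM (adjusted p = 0.0347 each; both chosen after their values were seen). Lef1, another Wnt factor, fell from 36.4 ± 3.01 to 13.7 ± 2.08 TPM (log2 -1.52, adjusted p = 0.0461). Upp1, uridine phosphorylase, fell from 169 ± 39.7 to 43.9 ± 14.8 TPM, and Pfdn6, a prefoldin subunit, from 73.3 ± 14.3 to 25.6 ± 6.42 TPM (adjusted p = 0.0426 each). In total 109 genes were higher and 32 lower of 21821, among them 92 and 27 of 11279 coding genes and 2 and 1 of 1068 lncRNAs. Leaving out any 1 of the 4 cultures left 0 genes past the threshold (limma, where 3886 genes had an unadjusted p under 0.05 with all cultures). The count was 0 with only these groups in the fit or without the filter on low values, 40 with values centred on the median, and 267 with a replicate block.

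**Figure D3:**
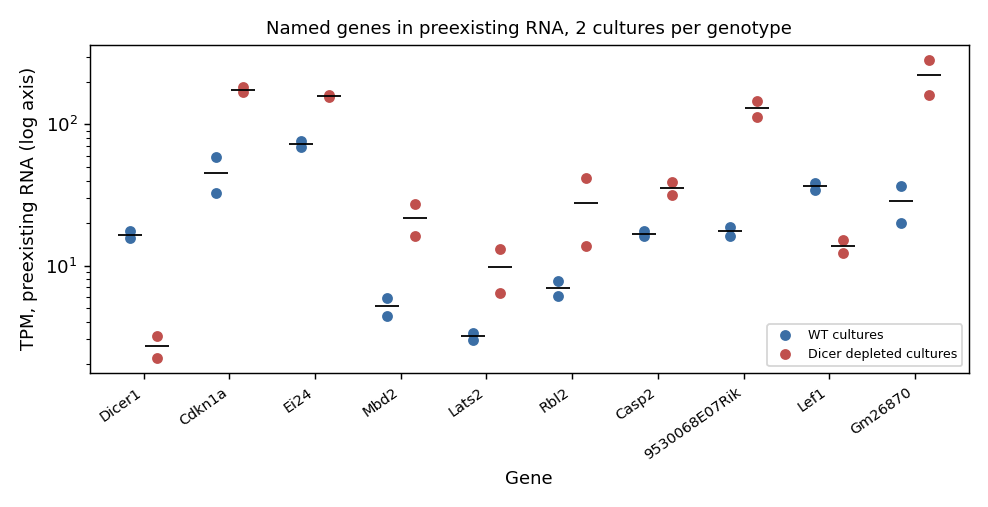
TPM in preexisting RNA of 10 genes, on a log axis, with 1 point for each of 2 WT and 2 Dicer-depleted cultures. Dicer1 and Lef1 lie lower in both depleted cultures; Cdkn1a, Ei24 and Mbd2 lie higher in both.

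Several lists moved as groups in preexisting RNA. Of 10 measured named miR-290 targets, 3 rose (6 adjusted over the list alone), 9 had a positive log2 change, and the median was 1.08. Members that did not pass over all genes included Casp2, a caspase (16.8 ± 1.03 to 35.4 ± 5.05 TPM, adjusted p = 0.0937), Lats2, a Hippo kinase (3.15 ± 0.269 to 9.76 ± 4.72 TPM, adjusted p = 0.105), and Rbl2, a pocket protein (6.92 ± 1.13 to 27.9 ± 19.9 TPM, adjusted p = 0.141). Of 18 p53 targets, 1 rose, which was Cdkn1a, and 7 did so adjusted over the list alone; Perp had a log2 change of 1.39 (adjusted p = 0.0879), and Mdm2 was at 117 and 168 TPM. Of 16 G1/S regulators, 1 rose, again Cdkn1a, and 6 did adjusted over the list alone; Ccnd2 was at 8.24 and 23.3 TPM. Cytosolic ribosomal proteins were lower as a group: 81 of 82 had a negative log2 change, with a median of -0.69, and 48 passed when adjusted over the list alone but none over all genes. Rpl3 was at 705 ± 9.74 TPM in WT and 461 ± 45.5 TPM in depleted cells. The 3376 pseudogenes, with 22.7 to 29.0% of the signal of a preexisting library, also had a negative median of -0.19, against 0.043 for coding genes. Whether the 2 falls are linked was not tested. Camera gave adjusted p = 5.16e-05 for the named targets, 0.00358 for p53 targets, 0.043 for G1/S regulators and 1.83e-21 for ribosomal proteins. None of these 4 calls held with an estimated correlation (adjusted p = 0.571, 0.571, 0.571 and 0.883).

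Other lists that describe cell identity showed no call in preexisting RNA. Of 18 naive pluripotency genes 0 passed over all genes; Pou5f1 was at 107 ± 45.9 and 111 ± 33.7 TPM in WT and depleted cells and Nanog at 254 ± 14.2 and 359.8 ± 75.1 TPM (camera adjusted p = 0.688, 11 of 18 positive). In the primed epiblast list Lef1 fell and Dnmt3b, a DNA methyltransferase, had a log2 change of -1.02 (SE 0.181, adjusted p = 0.0575; list adjusted p = 0.0755). Sparc, of the primitive endoderm list and also known from mesenchymal cells, rose from 395 ± 24.5 to 770.1 ± 33.5 TPM (adjusted p = 0.0426), while its 4 measured members did not pass as a list (adjusted p = 0.554). Of the fibroblast markers only Fbln1 and Vim were measurable, and Vim had a log2 change of 0.82 (adjusted p = 0.197). Trophoblast genes (2), neural or mesoderm genes (4), DNA methylation enzymes (8), apoptosis regulators (15), interferon response genes (12), immediate early genes (11), microRNA host genes (8), imprinted genes (14), polycomb and demethylase genes (11), deadenylation and decay factors (18) and 12 named lncRNAs also gave no call in any of the 3 contrasts of genotype. Plagl1, an imprinted zinc finger gene, was at 9.18 ± 3.12 TPM in WT and 48.5 ± 26.9 TPM in depleted cells (adjusted p = 0.0826).

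Many of the largest rises among named genes in preexisting RNA came from transcripts that share a repeat. A tandem array at the start of chromosome 9 (3000282 to 3038313), whose best repeat shift is 234 bases with 71.4% of bases equal, shares at least 25% of 16-base words with 13 of 12347 coding and lncRNA genes. Of these, 12 rose and 0 fell; Gm26870, the annotated lncRNA over the array, went from 28.5 ± 11.8 to 225 ± 88.7 TPM (log2 2.95, SE 0.415, adjusted p = 0.0426), and Gm11168 had a log2 change of 2.91 (adjusted p = 0.0426). Their sum went from 171 ± 74.1 to 1279 ± 488 TPM in preexisting RNA (7.47-fold), and from 441 ± 191 to 2708 ± 403 TPM in labelled RNA (6.14-fold). In labelled RNA the 13 genes had adjusted p-values from 0.0542 to 0.231, so none passed there. Reads can be shared between the 13, which makes them 1 signal and not 12 independent genes. In a fit without them 88 genes were higher and 28 lower in preexisting RNA.

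The labelled fraction, meant to hold RNA made in the last 10 or 15 minutes, was compared to find changes at synthesis. Spats2l rose from 2.97 ± 0.721 to 20.6 ± 0.420 TPM (n = 2; log2 2.45, SE 0.233, adjusted p = 0.0138) and Dpp4 from 2.24 ± 0.607 to 15.5 ± 2.00 TPM (log2 2.36, adjusted p = 0.0328). Cd55, a complement regulator chosen after its values were seen, rose from 17.8 ± 0.436 to 56.7 ± 7.01 TPM (adjusted p = 0.0351). Mir1898 and Mir6386, annotated microRNA precursors, were listed at 0 TPM in both WT cultures and at 22.0 ± 0.575 and 11.2 ± 5.59 TPM in depleted cells. Snord11, a small nucleolar RNA, was at 19.7 ± 9.54 TPM in WT and listed at 0 in both depleted cultures. In the ratio they had the opposite change of the same size (log2 -2.74, -3.43 and 2.63), so their preexisting RNA showed no change. Another short entry, Gm47294, went from 0 to 14.3 TPM in labelled RNA but from 6.06 to 0 TPM in preexisting RNA. With values at 0 and unknown depth, calls on short noncoding RNAs cannot be read as changes at synthesis. In total 20 genes were higher and 8 lower, of which 9 and 0 were coding and 9 and 8 were short noncoding RNAs. With only the labelled groups in the fit, or with pseudocount 0.1, the count was 0. Of the 82 ribosomal protein genes 2 had a positive log2 change, and 58 of 61 replication-dependent histone genes had a negative one; Hist1h2bn was at 66.6 ± 23.8 and 44.0 ± 15.6 TPM. Camera gave adjusted p = 7.18e-20 for ribosomal proteins, 6.94e-07 for histones, 0.00391 for p53 targets (17 of 18 positive), 0.0126 for named miR-290 targets (9 of 10 positive) and 0.0372 for the primed epiblast list (lower, 5 of 7 negative). No gene of these 5 lists passed over all genes; adjusted over the list alone, 3 p53 targets and 4 named targets were higher and 2 primed epiblast genes lower. None held with an estimated correlation (adjusted p = 0.888, 0.900, 0.571, 0.571 and 0.571), and the primed epiblast call did not hold with a replicate block (adjusted p = 0.0564) or with centred values (adjusted p = 0.0534). The count of 28 genes was 0 without WT replicate 2, and the balance turned to 5 higher and 38 lower without WT replicate 1 (7 of the 28 among them). It was 48 higher and 5 lower without depleted replicate 1 (11 of the 28) and 66 higher and 10 lower without depleted replicate 2 (12 of the 28). With the 15 minute libraries alone 9 were higher and 17 lower (8 of the 28), and with the 10 minute ones 17 and 6 (5 of the 28).

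The preexisting to labelled ratio asks whether depletion changed a gene's level beyond its change in new RNA. No gene passed (limma, 0 of 21821, with 940 at an unadjusted p under 0.05); by smallest p, most entries at the top were short noncoding RNAs, and Rad51d, a DNA repair gene, was the leading coding gene with a higher ratio (log2 1.57, SE 0.260, adjusted p = 0.747). Among named miR-290 targets, Casp2 had a log2 ratio change of 0.93 with 0.11 in labelled RNA, Rbl2 1.05, Mbd2 0.86, Cdkn1a 0.66 and Lats2 0.00; 8 of 10 were positive. This list was higher as a group (camera adjusted p = 0.00575; adjusted p = 0.571 with an estimated correlation), with 0 members past the threshold, also when adjusted over the list alone. The histone list was higher too, with 46 of 61 positive (adjusted p = 0.0151; adjusted p = 0.900 with an estimated correlation). Ribosomal proteins gave camera adjusted p = 0.063, 0.0253 with a replicate block and 0.900 with an estimated correlation.

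Predicted targets were then compared, with all 10078 mRNAs that have an annotated 3′ UTR. In preexisting RNA the 1353 mRNAs with a site for the miR-290 seed, shared by miR-302, had a median log2 change 0.0868 above that of random mRNA sets of like expression and UTR length, and the 1155 with a miR-17 site lay 0.146 above (permutation p = 2e-04 each, the smallest 10000 random sets give; adjusted p = 0.000873). The miR-25 (0.0637, adjusted p = 0.0060), miR-19 (0.0653, adjusted p = 0.000873) and miR-30 (0.0428, adjusted p = 0.00343) sets were higher as well. The miR-15 set (0.00491, adjusted p = 0.768) and the let-7 set (-0.0335, adjusted p = 0.0695) were not. Of the control families, miR-124 passed in the same direction (0.0358, adjusted p = 0.0197), while miR-122 (-0.0185), miR-1 (0.0318), miR-133 (0.000639) and miR-208 (0.0642) did not. With sets matched on GC content too, miR-124 lay at 0.0407 (adjusted p = 0.0120), above miR-30 at 0.0342 (adjusted p = 0.0133). Of the 73 mRNAs that rose, 23 carried a miR-290 site (31.5%, against 13.4% of all; Fisher's exact test over 12 families, adjusted p = 0.00091), and 16 a miR-17 site (21.9% against 11.5%, adjusted p = 0.0536). The controls miR-133 (13.7% against 6.58%, adjusted p = 0.110) and miR-1 (15.1% against 8.63%, adjusted p = 0.175) had odds ratios of 2.27 and 1.89, beside 2.18 for miR-17 and 3.00 for miR-290. The seeds overlap: mRNAs with both sites (625) lay 0.160 above matched sets, those with the miR-17 site alone (530) 0.115 and those with the miR-290 site alone (728) 0.0226, at the 89.8th percentile. Camera called 8 of 12 families, 3 of them controls (miR-124, miR-1 and miR-208); 0 of 12 held with an estimated correlation (adjusted p = 0.815 for both families named first), and 2 of 12 were called without WT replicate 1 or without depleted replicate 2.

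In the ratio, the shifts of the same families were 0.0548 for miR-290 and 0.0640 for miR-17 above matched sets (permutation p = 2e-04 each, the smallest possible; adjusted p = 0.000873). None of the other 10 families passed, controls included, and miR-124 lay at -0.000286. In the ratio, mRNAs with the miR-290 site alone lay 0.0399 above matched sets, at the 99.9th percentile. Those with the miR-17 site alone lay 0.0517 above and those with both sites 0.0692. In labelled RNA the shifts were 0.0526 and 0.0837 (adjusted p = 0.000873 each). The miR-19 (0.0385, adjusted p = 0.00448) and miR-30 (0.0420, adjusted p = 0.00148) sets and the controls miR-1 (0.0472, adjusted p = 0.000873) and miR-124 (0.0283, adjusted p = 0.0197) also passed there, with miR-122 (-0.0535) and let-7 (-0.0566) lower (adjusted p = 0.000873 each). Intronic signal of labelled RNA gave -0.000272 for miR-290 (adjusted p = 0.957) and 0.0219 for miR-17 (adjusted p = 0.0297). There miR-19 (0.0298, adjusted p = 0.00148), miR-30 (0.0322, adjusted p = 0.000873) and the controls miR-1 (0.0255, adjusted p = 0.0428) and miR-208 (0.0668, adjusted p = 0.0250) also passed, with let-7 lower (-0.0327, adjusted p = 0.0136). With sets matched on GC content too, no family passed for introns (smallest adjusted p = 0.0514). Exonic change in preexisting RNA minus intronic change in labelled RNA was 0.0660 above that with site labels permuted within strata for miR-290, 0.0964 for miR-17 (adjusted p = 0.0012 each) and 0.0684 for miR-25 (adjusted p = 0.0024); no control family passed. Camera called both families in the ratio (adjusted p = 0.0448 and 0.0365) and neither with an estimated correlation (adjusted p = 0.815 each). Neither was called by camera without WT replicate 1 or without depleted replicate 2, although the shifts above matched sets were 0.0514 and 0.0394 for miR-290 (unadjusted permutation p = 0.00040 and 0.0016) and 0.0439 and 0.0403 for miR-17 (p = 0.0010 and 0.0026). In camera 1 family in place of 2 was called with a replicate block, and 1 with centred values.

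**Figure D4:**
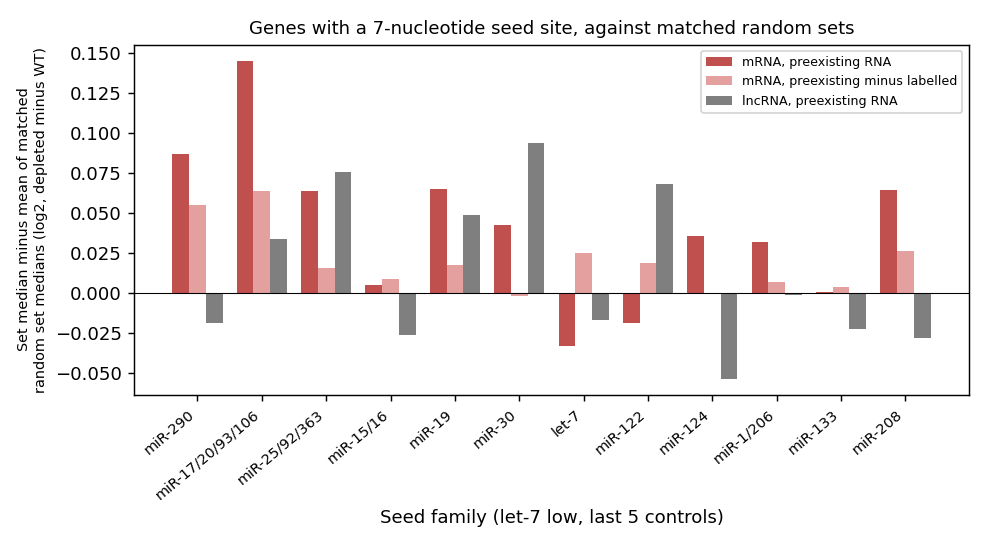
Median log2 change (Dicer depleted minus WT) of genes with a seed site minus that of matched random gene sets, for 12 seed families, in preexisting RNA and in the ratio for mRNAs and in preexisting RNA for lncRNAs. The miR-17 set lies highest in preexisting RNA for mRNAs at 0.146, and the lncRNA set of miR-290 lies at -0.0186.

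LncRNAs with seed sites were the counterpart, since they are not translated. The 149 lncRNAs with a miR-290 site lay -0.0186 from matched lncRNAs in preexisting RNA and -0.0362 in the ratio, and the 86 with a miR-17 site 0.0336 and -0.0503. None of the 12 families passed for lncRNAs in any contrast by either test. The smallest unadjusted p was 0.0228 against matched sets, for miR-30 in preexisting RNA (0.0936 above them, adjusted p = 0.515), and 0.0146 by camera, for miR-30 in labelled RNA (adjusted p = 0.392). The difference between the mRNA and the lncRNA shift was tested itself by permuting site labels within strata of expression and length. It was 0.105 for miR-290 (permutation p = 0.0017, adjusted p = 0.0204) and 0.113 for miR-17 (adjusted p = 0.0303) in preexisting RNA, and 0.0904 and 0.114 in the ratio (adjusted p = 0.0264 each). For miR-25, miR-15, miR-19 and miR-30 the difference did not pass in either measure, and in preexisting RNA it was negative for miR-25 (-0.0124) and miR-30 (-0.0515; -0.0506 in the ratio). The control families were not put through this test. Their mRNA and lncRNA shifts in preexisting RNA were 0.0358 and -0.0536 for miR-124, 0.0642 and -0.0282 for miR-208, and 0.0318 and -0.000977 for miR-1. They were 0.000639 and -0.0227 for miR-133, and -0.0185 and 0.0682 for miR-122. The difference is therefore not shown to be particular to expressed families. The permutation treats genes as independent, and sites in mRNAs were counted in 3′ UTRs but in lncRNAs over the whole transcript. Matching was done within each class, and the classes differ in more than translation. In WT the median log2 of labelled against preexisting RNA was 1.03 for lncRNAs and -0.0215 for coding genes. The difference between mRNAs and lncRNAs therefore cannot be credited to translation.

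Intronic signal in labelled RNA, a measure close to transcription, took a larger share in depleted cells. Introns took 21.4% ± 0.812 of labelled signal in depleted cells and 17.1% ± 0.580 in WT (n = 2), and 5.94% ± 0.199 and 4.77% ± 0.247 of preexisting signal. Plagl1 introns had the largest log2 change among the top calls (2.35, SE 0.163, adjusted p = 0.0138), followed by Emp1, a membrane protein (1.98, adjusted p = 0.0148). Hivep2, a zinc finger factor, gave 1.37 (adjusted p = 0.0148), and Smarca2, a chromatin remodeller, 1.28 (adjusted p = 0.0190). Of 12472 genes 522 were higher and 6 lower, around a median log2 change of 0.28; with values centred on the median, 1 gene was left. Leaving out any 1 culture left 1 to 4 genes.

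Labelled RNA was set against preexisting RNA in WT to see what labelling enriched. Both fractions came from the same 2 cultures and were not paired in the fit. Gas5, a short-lived snoRNA host transcript, was higher in labelled RNA (2345 ± 65.3 against 845 ± 114 TPM, adjusted p = 0.000926), as were Firre (log2 1.39, adjusted p = 0.00391), Pvt1 (1.42, adjusted p = 0.00171) and Mir17hg, the miR-17 host (1.85, adjusted p = 0.00257). Of 12 named lncRNAs 10 were higher and 0 lower, and of all 1068 lncRNAs 608 were higher and 22 lower, with a median of 1.03. Pabpc1, the poly(A) binding protein, was lower (log2 -1.30, adjusted p = 0.00154), and 36 of 61 histone genes were lower and 0 higher. Immediate early genes, planned as a check of enrichment, showed none. Of 11, 1 was higher and 0 lower, with a median of -0.083 (camera adjusted p = 0.329). Of 82 ribosomal protein genes 9 were higher and 3 lower, with a median of 0.286. In total 5692 genes were higher and 1742 lower, with a median of 0.24, and with centred values the balance turned to 3397 higher and 5147 lower; without either WT culture no gene passed (limma; 9574 had an unadjusted p under 0.05 with both). Between 15 and 10 minutes of labelling, Mir1954 was higher (log2 4.68, adjusted p = 4.13e-05) and Gm23468 lower (-3.14, adjusted p = 0.0233), both short noncoding RNAs, and no coding gene passed (limma; 821 of 11279 had an unadjusted p under 0.05).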

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

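The matching on base composition, the comparison of culture pairs and the splits of libraries were planned; the tests of listed entries, arms, exonic minus intronic change, centring, purity, matched sets for culture pairs or without a culture, and splits that part every culture were written after the results were seen.

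Entries that kept at least 25% of their day 0 RPM at day 12 were weighed first. If fragments of abundant RNA were the cause, the entries listed beforehand should keep a median of at least 50%, and they kept 201%. This bound was written after the results were seen, and only 3 of the 29 entries were listed. Passing it therefore cannot decide the cause, and says nothing of the unlisted entries. If unprocessed precursors were read on the 5′ arm, that arm should keep more than the 3′ arm, and over 53 precursors the median difference was 0.46 on the log2 scale (SD 2.25, sign-flip permutation p = 0.114), with 34 keeping more on the 5′ arm. The difference lay between the values set for either answer, so this explanation stays open. The other 26 entries may have several causes, and 19 of the 29 had a mean under 10 RPM at day 0.

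The higher level of predicted miR-290 targets in preexisting RNA of depleted cells was weighed next. Against random sets matched on expression, 3′ UTR length and GC content, the set lay at percentile 100, with a shift of 0.0860. The control miR-124 lay at percentile 99.86 there, with a shift of 0.0407. The controls miR-122, miR-1, miR-133 and miR-208 lay at percentiles 26.76, 96.97, 72.74 and 92.92. Because a control family also passed, this test cannot decide whether features of the 3′ UTR are the cause. Exonic minus intronic change was 0.0660 above permuted site labels, which argues against transcription alone as far as introns measure it. The exonic shift in labelled RNA was already 0.0526 above matched sets, so the difference does not isolate decay of preexisting RNA. The 1 TPM added to every value also shrinks changes of introns at low TPM. The smallest shift over the 4 pairs of a depleted and a WT culture was 0.139 against all other mRNAs, with -0.101 and -0.0712 within a genotype, and 0.0771 against matched sets, with -0.00707 and -0.0176, which argues against a single culture. Without WT replicate 1 or without depleted replicate 2, camera still called miR-290 and miR-17 but only these 2 families in place of 8 (0 in place of 2 in the ratio), and the miR-290 shift above matched sets was 0.0923 and 0.0792 (0.0514 and 0.0394 in the ratio). These tests take genes as the unit, and with an estimated correlation camera gave miR-290 adjusted p = 0.815. They also take mRNAs with and without a miR-17 site together. In preexisting RNA, mRNAs with the miR-290 site alone lay 0.0226 above sets matched on expression and length, at percentile 89.85. Those with both sites lay 0.160 above.

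The higher intronic share of labelled RNA in depleted cells was weighed last. Centring on the median left 1 of 528 calls, because it took the common change of 0.28 off every gene and left the spread as it was: the calls had a median log2 change of 0.90 before and 0.61 after, with median SE 0.155 and 0.159. Centring removes a common factor whatever its cause, so this decides nothing and a common factor stays open. Purer capture of new RNA would not raise introns in preexisting RNA, whose intronic share was 5.94% in depleted cells and 4.77% in WT and higher in both depleted cultures. More intronic RNA or genomic DNA in both depleted cultures might account for it, and neither was measured.

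For each comparison of 2 days, the true split was 1 of 10 with as many calls, and the highest other split had 0 calls at days 4, 8, 10 and 12 and 1 between days 12 and 8; 10 splits are too few for a share under 0.05. Across days 1 of 100 groupings, the true one, reached 242 calls, and the highest other reached 124. For labelling time 18 of 34 splits had at least the 2 calls of the true one, and the highest other had 8, but 12 of these 18 keep both libraries of some culture on 1 side. Of the 8 splits that part the libraries of all 4 cultures, as the true one does, 6 had at least 2 calls and the highest other had 4; 8 splits are too few for a share under 0.05.

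Among reads not assigned to a microRNA, the share aligned outside microRNA annotation was 25.4% at day 12 and 20.3% at day 0 (exact permutation p = 0.1, the smallest possible). The change of predicted miR-290 targets in the preexisting to labelled ratio lay 0.0548 above that of matched sets.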

How the results depend on the processing

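Alternatives without the listed abundant-RNA entries, with coding genes and lncRNAs only, without the satellite transcripts, with the longest 3′ UTR and with centred target values were chosen after the results were seen; the others were planned. Over 18 results, 140 alternatives were the same and 76 moved; the cause was not tested. Of 349 alternatives for 30 single microRNAs, 328 were the same, 16 weaker and 5 reversed; of 486 for 28 single genes, 221 were the same and 265 weaker; of 44 for 4 target shifts, 34 were the same and 10 weaker. A lone culture was assumed to vary like the other groups.

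With all reads as library size, day 12 against day 0 turned to -5.04 for miR-182-5p, -5.43 for miR-21a-5p, -4.23 for miR-183-5p and -0.14 for miR-6539; with total microRNA counts miR-21a-5p was -0.029. Calls at day 4 (169) were 302 with 2 days only and 108 to 145 without a replicate. Without the filter they were 292 at day 8 (173), 309 at day 10 (188), 310 at day 12 (180) and 449 across days (242). Day 12 against day 8 (91) gave 198 with all reads, 58 with 2 days only and 52 to 85 without a replicate. With a replicate block the microRNA counts were 169, 174, 185, 178, 95 and 237. MicroRNA lists (17) gave 0 with an estimated correlation and 5 with total counts. The log2 total at day 8 (-3.88) ran from -4.13 to -3.67 without a replicate.

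Labelled genes (28) were 0 with pseudocount 0.1 or 2 groups only, 86 unfiltered, 15 centred, 585 with every library, 366 with duplicateCorrelation, 23 with a replicate block, 8 for coding genes and lncRNAs and 0 to 76 without a culture. Preexisting genes (109 higher, 32 lower) were 27 with pseudocount 5, 0 unfiltered or with 2 groups only, 40 centred, 1320 with every library, 914 with duplicateCorrelation, 1 at 10 and 7 at 15 minutes, 267 with a replicate block, 267 for coding genes and lncRNAs, 116 without satellite transcripts and 0 to 0 without a culture. The ratio (0) gave 1 with pseudocount 0.1 and 7 at TPM of at least 10. Labelled against preexisting (7434) gave 2332 at TPM of at least 10, 3964 at 10 minutes, 1992 for coding genes and lncRNAs, 8466 with a replicate block and 0 to 6570 without a culture. Labelling time (2) gave 1 with pseudocount 5, unfiltered or with a replicate block, 0 at TPM of at least 10 or for coding genes and lncRNAs, and 2 to 11 without a culture. Introns (528) gave 1 with pseudocount 0.1, 2786 with 5, 1061 unfiltered, 48 at TPM of at least 10, 1 centred, 5 with quantile normalization, 4183 with every library, 3478 with duplicateCorrelation, 19 at 10 and 82 at 15 minutes, 28 with 2 groups only, 1276 with a replicate block and 1 to 4 without a culture.

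Gene lists (11) gave 0 with an estimated correlation and 11 with a replicate block. Target families in preexisting RNA (8) were 5 with 8-base sites, 0 with an estimated correlation and 2 to 9 without a culture; in the ratio (2) they were 0 with an estimated correlation, 1 with a replicate block, 1 centred and 0 to 3 without a culture; for lncRNAs they were 0 throughout. Not run were the ratio with 2 groups only, labelling time with every library as a sample (its unit already), at a single time or with 2 groups only, introns without satellite transcripts, and all days with 2 days only.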

Other observations

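The test of the 2 arms of a precursor was written after the results were seen; the lists for labelled against preexisting RNA were planned. In WT cells, gene lists other than that of named lncRNAs also stood apart between fractions. Of 18 naive pluripotency genes 5 were lower in labelled RNA and 0 higher (median log2 -0.42, n = 2 cultures), and of 18 deadenylation and decay factors 8 were lower and 1 higher (median -0.57). DNA methylation enzymes (5 of 8 lower), primed epiblast genes (2 of 7), polycomb and demethylase genes (4 of 11) and imprinted genes (2 of 14 lower, 1 higher) were also lower as groups. Camera gave adjusted p = 0.00180, 0.000655, 0.00672, 0.00530, 0.0211 and 0.0105, and none of these held with an estimated correlation (adjusted p = 0.168 each, and 0.246 for the polycomb and demethylase genes). Histones (adjusted p = 1.06e-15) and the 12 named lncRNAs, which were higher (adjusted p = 0.0102), did not hold with an estimated correlation either (adjusted p = 0.343 and 0.246). Without either WT culture no gene passed (limma; 9574 had an unadjusted p under 0.05 with both).

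The arms of miR-182 differed. miR-182-5p, the guide arm, went from 38078 RPM at day 0 to 1158 RPM at day 12, and miR-182-3p was at 18.4 ± 1.82 and 18.8 ± 4.79 RPM (n = 3; log2 0.03). For miR-21a the log2 change was -5.43 on the 5′ arm and -3.05 on the 3′ arm, chosen after its values were seen.

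A hypothesis is that Dicer loss acts on mRNAs with miR-290 or miR-17 sites after transcription and leaves lncRNAs with the same sites aside. The exonic minus intronic change of 0.0660 for miR-290 covers mRNAs only and may point to the first part. It was not tested on mRNAs with the miR-290 site alone. These lay 0.0226 above matched sets in preexisting RNA and 0.0399 in the ratio, against 0.115 and 0.0517 for the miR-17 site alone. The second part rests on the mRNA minus lncRNA difference in preexisting RNA, which was 0.105 for miR-290 but -0.0124 for miR-25. This difference was not tested for the control families. More cultures per genotype, with spike-in RNA and blocked translation, could test the hypothesis. A second hypothesis is that entries such as miR-6240 hold fragments of abundant RNA, given the median of 201% kept by listed entries; aligning the reads to ribosomal RNA first could test it.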
